A study of Mus musculus with 21 samples.

How the data were processed

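The series holds 3 engineered lines of E14 mouse embryonic stem cells. In each line one ribosome-associated protein, RACK1, RPLP0 or RPLP1, carries an auxin-inducible degron, and the genotype labels name the plant receptor Tir1 together with RPS26. Cells were treated for 8 h with auxin (IAA), which triggers degradation of the tagged protein, or with the solvent DMSO. Per the labels, each line has 3 mRNA samples after IAA and 3 after DMSO, made from polyadenylated RNA, and 1 footprint (ribosome profiling) sample that combines all replicates of both treatments. Ribosome profiling sequences the mRNA fragments protected by ribosomes, so footprints per gene follow how much of its mRNA is being translated. The labels do not say whether replicates came from separate cultures, so the authors' error rates may measure technical spread only.

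The values analysed were 3 tables of the authors' own comparisons, 1 per line. Per the file headers, the authors deposited for each gene a log2 fold change of mRNA and of footprints after removal of the protein, a false discovery rate (an adjusted p-value, FDR) for each, and a class code from 0 to 3. The authors' class codes separate no change, mRNA change, footprint change and both, per the file headers of the RACK1 and RPLP1 tables. From the values, the mRNA class holds genes with an FDR under 0.2, with 1 exception in RPLP0, and the footprint class holds genes under 0.35 for RACK1 and under 0.1 for RPLP0 and RPLP1. A positive log2 fold change was read as higher after removal, since the headers speak of change after removal and name no numerator. The aligner, the counting, the annotation release, the statistical test, the low-count filter and the genome build are not given in the sources used here. Genes are named by an Ensembl transcript identifier and a symbol. Symbols that a spreadsheet had turned into dates, 17, 16 and 18 for RACK1, RPLP0 and RPLP1, stayed in the counts and were not named. Symbols occurring more than once, 4, 2 and 2 entries, were left out of list tests and of comparisons between lines.

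No value per sample was used, so total reads per sample, and the depth behind each value, are unknown. How the footprint statistics were made from the combined samples is not given in the sources used here, so it is unknown what spread the footprint FDRs and the standard errors drawn from them measure. Precision is given instead by the standard error that a fold change and its FDR imply. The FDR was turned back into a p-value by undoing the Benjamini-Hochberg step-up, interpolating within runs of equal FDR, and the standard error is the fold change divided by the matching normal quantile. Median implied standard errors of the log2 change were 0.165 for mRNA and 0.0974 for footprints in RACK1, 0.105 and 0.113 in RPLP0, and 0.115 and 0.0875 in RPLP1. Runs of genes with the same mRNA fold change, up to 43 genes at -0.58 in RACK1, can be genes with very few reads.

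Before the data were examined, a count model was planned, with a fallback for tables that hold only the authors' statistics. Under that fallback mRNA and footprint changes were called where the authors' FDR was below 0.05, with no further test. The plan foresaw for such tables no test of translation efficiency and no statement that lines differ. Both were added after the data were seen and are approximate. The change in translation efficiency is the footprint log2 change minus the mRNA log2 change, tested against the combined implied standard errors with Benjamini-Hochberg adjustment, assuming normal and independent errors in the 2 assays; with 3 mRNA samples a group, and an unstated number behind the footprint statistics, this is an approximation, so the text gives the change and its standard error (SE) and no p for single genes. Responses of 2 lines were compared gene by gene in the same way, and overlaps of calls were tested per direction with Fisher's exact test (two-sided) against n1 × n2 / N, the overlap of independent lists. The lines have separate controls.

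Gene lists, 34 in all, were fixed before the data were examined. They are the removed proteins and their partners; large-subunit and small-subunit ribosomal proteins; other mRNAs with a terminal oligopyrimidine tract; initiation factors; elongation and termination factors; aminoacyl-tRNA synthetases; ribosome biogenesis factors; stalled-ribosome rescue factors; mitochondrial ribosomal proteins; nuclear-encoded and mitochondrially encoded respiratory chain genes; ATF4 targets; mRNAs controlled by upstream open reading frames; p53 targets; immediate-early genes; the endoplasmic reticulum unfolded protein response; cytosolic heat shock; pluripotency; germ-layer, 2-cell-like and fibroblast markers; aryl hydrocarbon receptor targets; cholesterol synthesis; solute carriers; TMEM proteins; extracellular matrix and basement membrane; proteasome; replication-dependent histones; zinc finger proteins; mitosis; S phase; tubulins and actins; and the Wnt pathway. A list's median change was set against 10000 random lists of the same size, matched on deciles of the implied standard error because the tables give no mean expression. The two-sided p, called a permutation p here, ranks the list median among these random lists. Their genes were drawn with replacement from all genes, list members included, and no labels were permuted. The p was adjusted by Benjamini-Hochberg over the lists of a line and quantity, and its smallest possible value before adjustment is 0.0002. Lists needed at least 5 measured members. This test ignores that genes of a list can vary together from sample to sample, so its p-values are too small by an unknown amount; a test with an estimated correlation needs values per sample. Counts of called members were set against all genes with Fisher's exact test, and were also taken with p-values adjusted over the list alone.

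Named genes followed a rule fixed beforehand. They are the removed proteins, the 5 largest called increases and 5 largest called decreases per line and quantity, leaving out predicted names, and up to 4 members with the smallest p of each list described. The rule's conditions on replicates and on expression level could not be applied, since the tables give neither, so genes named for the size of their change can be genes with few reads. A gene named outside that rule is said to be so.

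The steps that compute p-values were tested on simulated data with 200 changed genes per line, of which 100 changed by 0.5 and 100 by 1 on the log2 scale in translation efficiency. With normal errors the test recovered 31% and 65% of them in RACK1 (12905 genes), 36% and 82% in RPLP0 (12353 genes) and 56% and 80% in RPLP1 (12274 genes), with 3, 4 and 8 false calls. With heavier-tailed errors (t with 8 degrees of freedom) recovery was 4% and 44%, 14% and 57%, and 17% and 61%. Simulated errors were independent in the 2 assays, and their p-values were computed from the same error distribution. A low number of false calls was therefore largely fixed in advance, and errors correlated between assays were not simulated. Of 100 lists of genes drawn at random from each line's own mRNA changes, the list test called 6% in RACK1, 3% in RPLP0 and 6% in RPLP1 before adjustment. They came from the same values as the random lists they were set against, so a low rate was fixed in advance. It does not measure false calls for lists of genes that vary together. Alternatives tried were an FDR below 0.01, a minimum absolute log2 change of 1, the authors' class codes, an error correlation of 0.5 between assays, unmatched random lists and precisely measured list members only. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.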

Results

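Translation and mRNA levels were compared in E14 mouse embryonic stem cells, a line derived from the inner cell mass of a blastocyst, 8 h after removal of 1 of 3 ribosome-associated proteins. RACK1 is a scaffold protein on the head of the small ribosomal subunit, and RPLP0 and RPLP1 are proteins of the stalk of the large subunit, where translation factors bind. Each line had 3 mRNA samples after IAA and 3 after DMSO, and 1 footprint sample combining the replicates of both treatments; how footprint FDRs were made from it is not given in the sources used here, so the spread they measure is unknown. No line without a degron was among the samples, so effects of IAA itself are not told apart from those of removal. Changes described as after removal are changes after IAA against DMSO in that line. The stated purpose of the series was to find how translation efficiency changed across genes after each removal. The tables held 12905 genes for RACK1, 12353 for RPLP0 and 12274 for RPLP1, and 11874 genes were in all 3. They give fold changes and FDRs only, so gene values below are the authors', calls are genes with the authors' FDR below 0.05, and read depth is unknown. List medians, their tests, translation efficiency and comparisons between lines were computed from those values. A list's permutation p comes from random lists of genes and is adjusted over the 34 lists; it ignores that genes of a list vary together, so it is too small by an unknown amount.

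The mRNAs of the removed proteins were examined first, although a degron acts on the protein and its mRNA does not check the removal. In the RACK1 line the Rack1 mRNA had a log2 change of -0.15 (FDR 0.614) in the authors' deposited table. Rplp0 mRNA changed by -0.08 (FDR 0.122) after RPLP0 removal and Rplp1 mRNA by -0.14 (FDR 0.0605) after RPLP1 removal, per the authors' deposited table, neither past the threshold. After RPLP1 removal the mRNAs of its stalk partners fell, Rplp2 by -0.20 (FDR 0.00911) and Rplp0 by -0.16 (FDR 0.0143), and Rplp0 footprints fell by -0.38 (FDR 0.00024) in the authors' deposited table. As a list, the 5 removed proteins and partners had a median mRNA change of -0.14 in RPLP1 (permutation p = 0.0156), -0.03 in RACK1 and 0.03 in RPLP0, the last 2 not past the threshold. With unmatched random lists the RPLP1 value did not pass (permutation p = 0.479).

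Immediate-early genes, the transcription factors and phosphatases that growth signals switch on first, rose after RACK1 removal. Egr1 mRNA rose by 1.19 on the log2 scale (FDR 4.05e-09), Fos by 1.11 (FDR 0.00143), Junb by 0.80 (FDR 0.00125) and Dusp1 by 0.74 (FDR 0.00378) in the authors' deposited table. Their median mRNA change over 29 members was 0.36, outside the -0.10 to 0.10 that held 95% of random lists (permutation p = 0.00227), with 5 members higher over all genes tested and 10 when adjusted over the list alone. Footprints followed for Fos (0.92, FDR 0.00151) and Egr1 (0.87, FDR 0.00151) in the authors' deposited table. The list's footprint median was 0.17 (permutation p = 0.000971), with 2 members higher, and 11 higher and 2 lower when adjusted over the list alone.

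In all, 62 mRNAs changed after RACK1 removal, 22 higher and 40 lower, and 4 genes changed in footprints, 3 higher and 1 lower. At an unadjusted p below 0.05 there were 1385 and 1070. The authors' deposited table also gave increases of Klf2 (0.82, FDR 1.72e-06), a transcription factor of naive pluripotency, and of the Notch ligand Dll1 (0.76, FDR 0.00312). The largest decreases in the authors' deposited table were Eid3 (-3.68, FDR 0.0331), Kxd1 (-2.34, FDR 2.98e-14), the mitochondrial leucyl-tRNA synthetase Lars2 (-2.19, FDR 6.93e-16), Ppp1r12b (-2.03, FDR 0.0467) and Zfp9 (-1.65, FDR 0.0114). The other 2 footprint changes in the authors' deposited table were an increase of Ifrd1 (0.75, FDR 0.000382), an mRNA controlled by an upstream open reading frame, and a decrease of Pck2 (-0.46, FDR 0.0228), the mitochondrial phosphoenolpyruvate carboxykinase. The plot of footprint against mRNA changes shows how weakly the assays moved together in this line. The Spearman correlation across genes was 0.121, against 0.467 in RPLP0 and 0.511 in RPLP1, and genes are not independent replicates. RACK1 also had the fewest calls and the largest median implied standard error for mRNA, 0.165 against 0.105 in RPLP0 and 0.115 in RPLP1. Such noise lowers a correlation, and its part was not tested.

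**Figure D1:**
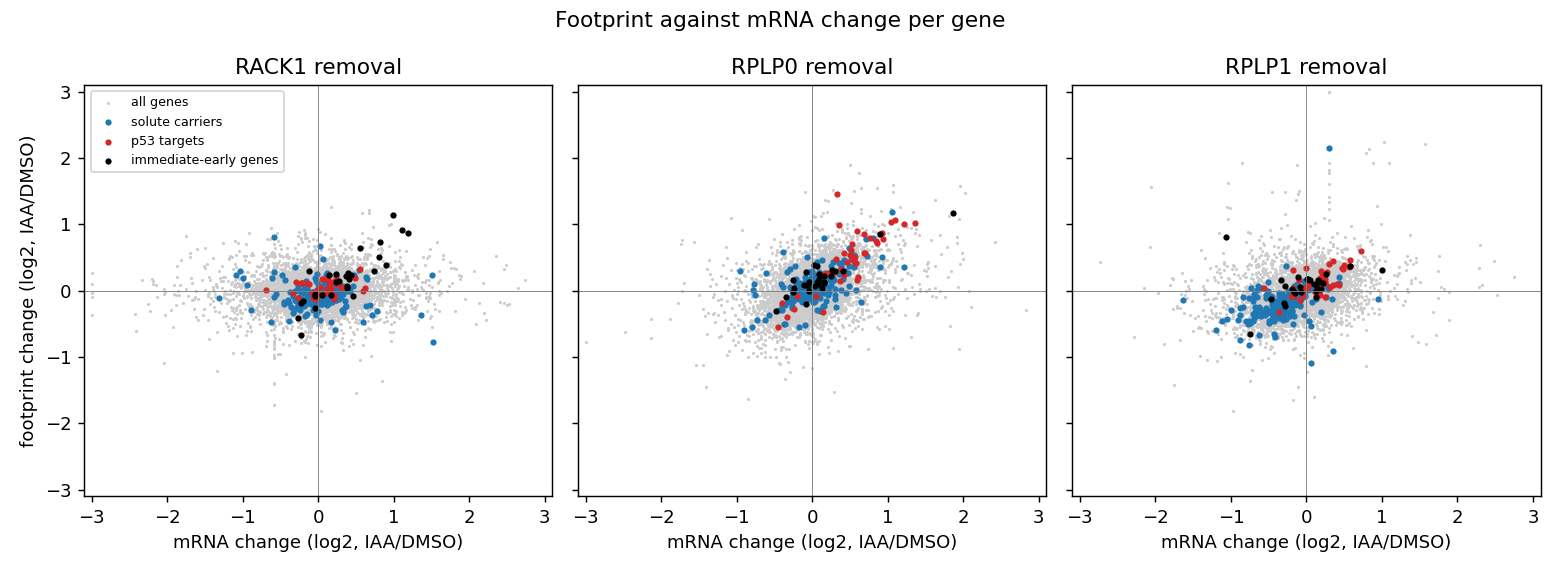
Footprint log2 change (vertical) against mRNA log2 change (horizontal) for each gene after removal of RACK1, RPLP0 and RPLP1, with values beyond 3 drawn at 3; each point is 1 gene, and p53 targets, solute carriers and immediate-early genes are coloured. Immediate-early genes lie at the upper right for RACK1 (median mRNA change 0.36), p53 targets at the upper right for RPLP0 (0.52) and solute carriers at the lower left for RPLP1 (-0.31).

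Mitochondrially encoded respiratory chain mRNAs were lower after RACK1 removal while their footprints were higher. Their median over 13 genes was -0.23 for mRNA (permutation p = 0.00272) and 0.20 for footprints (permutation p = 0.000971). Of the 13 mRNAs, 1 fell over all genes tested and 6 when adjusted over the list alone, led by mt-Nd3 (-1.05, FDR 1.07e-07) in the authors' deposited table, and no member passed in footprints. Replication-dependent histone mRNAs, which lack a poly(A) tail, had a median of -0.35 over 41 genes (permutation p = 0.0136) with no member past the threshold, 2 lower when adjusted over the list alone, and a footprint median of 0.00 (permutation p = 0.657). Nuclear-encoded respiratory chain genes had a median mRNA change of -0.09 (permutation p = 0.00227), with 2 of 81 lower and 7 when adjusted over the list alone; Cox6c fell by -0.46 (FDR 0.0123) in the authors' deposited table.

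Several groups of secreted and membrane proteins had lower footprints after RACK1 removal with no called member. The footprint median was -0.16 for 29 matrix and basement membrane genes (permutation p = 0.000971), -0.08 for 220 solute carriers (permutation p = 0.000971) and -0.07 for 174 TMEM proteins (permutation p = 0.00255). The TMEM value did not pass among precisely measured members (permutation p = 0.495). Genes of the endoplasmic reticulum unfolded protein response were lower in both assays, with medians of -0.11 for mRNA (permutation p = 0.0238) and -0.16 for footprints (permutation p = 0.000971); the chaperone Hspa5 was the 1 called member, with an mRNA change of -0.42 (FDR 0.0234) in the authors' deposited table. ATF4 targets, which act in amino acid supply, had medians of -0.09 (permutation p = 0.0204) and -0.14 (permutation p = 0.000971), with 8 footprint decreases and 1 increase when adjusted over the list alone and none over all genes. The 1 called ATF4 target in mRNA rose, Ddit4 (0.57, FDR 0.00136), and Ddit3 had 0.51 (FDR 0.233), in the authors' deposited table. The mRNA values of both lists did not pass with unmatched random lists (permutation p = 0.151 and 0.110). Zinc finger proteins went opposite ways in the 2 assays, with medians over 369 genes of -0.07 for mRNA (permutation p = 0.00227) and 0.10 for footprints (permutation p = 0.000971).

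Translation efficiency passed the added approximate test for 13 genes after RACK1 removal, 10 higher and 3 lower. Higher genes included Kxd1 (2.49, SE 0.29), Lars2 (2.29, SE 0.25), Zyg11a (1.40, SE 0.25), mt-Nd3 (1.22, SE 0.20) and Zfp609 (0.77, SE 0.15), whose mRNAs had fallen while their footprints had not passed. Tcf15 (-0.80, SE 0.19), Pgp (-0.72, SE 0.16) and the mTOR inhibitor Ddit4 (-0.55, SE 0.14) were lower. Lists with higher efficiency were histones (median 0.47), mitochondrially encoded genes (0.46), zinc finger proteins (0.17), large-subunit ribosomal proteins (0.10) and nuclear-encoded respiratory chain genes (0.05). The histone value comes from a fall in mRNA without one in footprints, and 1 of 41 histones was in the more precise part of the table. A candidate technical cause, which would also reach the mitochondrial mRNAs, is given under Other observations. Lists with lower efficiency were the Wnt pathway (-0.21), matrix genes (-0.16) and solute carriers (-0.11). This count rests on the assumed error: with an error correlation of 0.5 between the assays 421 genes passed.

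p53 targets rose in both assays after RPLP0 removal, more than any other list. Of 42 measured targets, 30 rose and 1 fell in mRNA, and 24 rose and 1 fell in footprints; adjusted over the list alone the counts were 33 and 3 for mRNA and 33 and 2 for footprints. Median changes were 0.52 for mRNA (permutation p = 0.00136) and 0.49 for footprints (permutation p = 0.000755), and the mRNA increases were enriched (adjusted Fisher's exact p = 1.37e-28). The members with the smallest p for mRNA in the authors' deposited table were Trp53inp1 (0.86, FDR 1.39e-13), Plk2 (1.21, FDR 1.85e-13), the p53 ubiquitin ligase Mdm2 (0.76, FDR 1.55e-12) and Ccng1 (0.68, FDR 2.94e-12). Footprint increases led by p in the authors' deposited table were Plk2 (1.01, FDR 4.26e-05), Mdm2 (0.79, FDR 8.43e-05), Fbxw7 (0.99, FDR 8.43e-05) and Eda2r (0.75, FDR 0.000619).

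Cholesterol synthesis fell after RPLP0 removal. Of 26 genes 12 had lower mRNA and none higher, 14 when adjusted over the list alone, with a median of -0.26 (permutation p = 0.00136); 4 fell in footprints, 12 over the list alone, with a median of -0.16 (permutation p = 0.00124). Hmgcs1 (-0.62, FDR 6.15e-10) and Insig1 (-0.57, FDR 3.56e-07) were among the mRNA decreases in the authors' deposited table. Of 24 genes of the unfolded protein response 10 fell and 1 rose in mRNA (median -0.14, permutation p = 0.00136), 11 and 1 over the list alone, among them the endoplasmic reticulum chaperones Hsp90b1 (-0.44, FDR 7.03e-09) and Hspa5 (-0.43, FDR 5.99e-08) in the authors' deposited table. Among 41 ATF4 targets 11 fell and 4 rose in mRNA (median -0.16, permutation p = 0.00136), 17 and 5 when adjusted over the list alone. The amino acid transporters Slc7a1 (-0.36, FDR 0.000102) and Slc1a5 (-0.41, FDR 0.000132) fell, while Sesn2 (0.50, FDR 9.93e-09) and Ddit4 (0.60, FDR 4.18e-06) rose, per the authors' deposited table; Sesn2 is also in the p53 list. ATF4 target footprints had a median of -0.06 that did not pass (permutation p = 0.153), while 5 members fell and 2 rose, 11 and 4 over the list alone, with Gpt2 at -0.61 (FDR 0.0053) in the authors' deposited table.

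Markers of the 2-cell-like state, a rare state of these cultures, were higher after RPLP0 removal, with medians over 18 genes of 0.28 for mRNA (permutation p = 0.00170) and 0.36 for footprints (permutation p = 0.00124). Of these genes 5 rose in mRNA, 9 over the list alone, led in the authors' deposited table by Zfp750 (1.62, FDR 2.55e-06) and Zscan4c (0.28, FDR 0.000642), a member of a family of near-identical copies whose value is uncertain. Germ-layer and primed markers were lower in mRNA (median -0.14, permutation p = 0.0446), with 5 of 19 lower and 1 higher, 5 and 2 over the list alone; Lefty1 fell by -0.54 (FDR 2.80e-06) and the DNA methyltransferase Dnmt3a by -0.43 (FDR 2.82e-05) in the authors' deposited table. Pluripotency genes had a footprint median of 0.09 (permutation p = 0.000755) and an mRNA median of -0.02 (permutation p = 0.536); 3 pluripotency mRNAs rose and 3 fell. Among them Tfcp2l1 fell by -0.42 (FDR 2.32e-07) while Tet2 (0.24, FDR 0.000808), Nr0b1 (0.26, FDR 0.00195) and Lifr (0.31, FDR 0.0044) rose, in the authors' deposited table. TMEM proteins had medians of 0.11 for mRNA (permutation p = 0.00136; 14 of 153 rose and 1 fell) and 0.13 for footprints (permutation p = 0.000755). Matrix genes had an mRNA median of 0.10 (permutation p = 0.00170), with 8 of 29 higher and 1 lower, 11 and 1 over the list alone, but did not pass with unmatched random lists (permutation p = 0.0544).

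Footprints of ribosomal proteins were higher after RPLP0 removal as groups, with no called member. Medians were 0.13 for 50 large-subunit genes and 0.17 for 30 small-subunit genes (permutation p = 0.000755 for both). The authors' deposited table listed Rpl22l1 (-0.47, FDR 2.35e-06), Rpl3 (-0.25, FDR 6.42e-06) and Rpl10a (-0.15, FDR 0.00678) as the 3 ribosomal protein mRNAs past the threshold, all lower. Mitochondrially encoded genes had a footprint median of 0.25 (permutation p = 0.0126) with no called member, and 5 higher when adjusted over the list alone. In mRNA, 5 of 20 aminoacyl-tRNA synthetases fell (median -0.07, permutation p = 0.0287), 5 of 34 S-phase genes fell (median -0.07, permutation p = 0.00378), and 6 of 23 tubulins and actins fell and 2 rose (median -0.08, permutation p = 0.0148); over the list alone the decreases were 6, 7 and 9. Ccne1, the cyclin of S-phase entry, fell by -0.38 (FDR 4.56e-06) and Tubb5 by -0.21 (FDR 7.37e-05) in the authors' deposited table. None of these 3 medians passed with unmatched random lists (permutation p = 0.25, 0.0905 and 0.153).

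In all, 1229 mRNAs changed after RPLP0 removal, 624 higher and 605 lower, and 304 genes changed in footprints, 176 higher and 128 lower. Of these, 209 passed in both assays, all 209 in the same direction. The largest mRNA increases in the authors' deposited table were Hist1h2bl (2.82, FDR 0.0227), Cpxm2 (2.10, FDR 0.0483), Ltb4r2 (2.03, FDR 0.00022), Mgat4e (1.93, FDR 0.0483) and Fosl1 (1.87, FDR 0.00373); the histone value is uncertain because near-identical copies share reads. Fam183b (-4.0, FDR 0.00138), Matn2 (-2.48, FDR 0.00513) and Vav3 (-2.14, FDR 0.0242) fell most in mRNA, per the authors' deposited table. In footprints the authors' deposited table had Gdpd5 (1.89, FDR 0.0133) and Nipal4 (1.77, FDR 0.0303) as the largest increases, and Rbbp8nl (-1.64, FDR 0.0313), Fbll1 (-1.53, FDR 0.0491), Chac1 (-1.13, FDR 0.0409) and Ibtk (-1.11, FDR 8.43e-05) as the largest decreases.

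Translation efficiency passed the added approximate test for 1 gene after RPLP0 removal, Mdm4, an inhibitor of p53, at -0.62 (SE 0.13); 813 genes had an unadjusted p below 0.05. With an error correlation of 0.5 between assays 245 genes passed, so the count depends on that assumption. Lists with higher efficiency included mitochondrially encoded genes (median 0.24, permutation p = 0.00272, but 0.03 among precisely measured members, permutation p = 0.679), large-subunit and small-subunit ribosomal proteins (0.13 each), pluripotency genes (0.13), tubulins and actins (0.13), ATF4 targets (0.12), the Wnt pathway (0.11) and the unfolded protein response (0.10). Zinc finger proteins had lower efficiency (-0.10, permutation p = 0.00170).

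Many solute carriers, TMEM proteins and matrix genes fell in both assays after RPLP1 removal. Of 208 solute carriers 65 fell and 1 rose in mRNA (median -0.31, permutation p = 0.00085), 82 and 4 over the list alone, and 40 fell and 1 rose in footprints (median -0.18, permutation p = 0.000755), 55 and 1 over the list alone. The subunits of the large neutral amino acid transporter, Slc7a5 (-0.63, FDR 1.41e-05) and Slc3a2 (-0.45, FDR 5.65e-05), fell in mRNA with Slc1a5 (-0.60, FDR 3.75e-05) and Slc7a1 (-0.52, FDR 5.65e-05) in the authors' deposited table. Matrix and basement membrane genes fell in 19 of 29 cases in mRNA (median -0.28, permutation p = 0.00085) and 18 in footprints (median -0.25, permutation p = 0.000755), with none higher, and in 20 and 26 when adjusted over the list alone. Fibroblast markers, a list with no gene in common with it, had medians of -0.27 for mRNA (permutation p = 0.171) and -0.22 for footprints (permutation p = 0.0264) in the same line. Examples in the authors' deposited table were the collagen Col18a1 (-0.61, FDR 5.47e-06), the laminin chains Lama5 (-0.50, FDR 2.86e-05) and Lamc1 (-0.37, FDR 0.000107) and the integrin Itga5 (-0.57, FDR 3.36e-05). Of 164 TMEM proteins 32 fell in mRNA (median -0.21, permutation p = 0.00085) and 17 in footprints (median -0.16, permutation p = 0.000755), and none rose; adjusted over the list alone 40 fell and 1 rose in mRNA and 19 fell in footprints.

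Zinc finger proteins, mostly DNA-binding transcription factors, went the other way after RPLP1 removal. Of 366 genes 49 rose and 5 fell in mRNA (median 0.15, permutation p = 0.00085), and 36 rose and none fell in footprints (median 0.12, permutation p = 0.000755); over the list alone the counts were 50 and 5, and 38 and 0. Zfp459 (0.52, FDR 0.000223) and Zfp979 (0.41, FDR 0.000334) led by p in the authors' deposited table, and such clustered genes can share reads with near-identical copies. p53 targets were higher too: 16 of 41 rose in mRNA (median 0.20, permutation p = 0.00085), 19 over the list alone, and 13 rose in footprints (median 0.11, permutation p = 0.000755), 14 over the list alone, with none lower. Trp53inp1 (0.57, FDR 1.41e-05), Plk2 (0.72, FDR 4.64e-05), Ccng1 (0.50, FDR 5.44e-05) and Mdm2 (0.48, FDR 6.41e-05) led the mRNA increases in the authors' deposited table. The footprint median did not pass among precisely measured p53 targets (permutation p = 0.0593).

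Many ATF4 targets, genes of the unfolded protein response and cholesterol synthesis genes fell after RPLP1 removal. Among 41 ATF4 targets 14 fell and 1 rose in mRNA (median -0.17, permutation p = 0.00151), 18 and 1 over the list alone, and 12 fell and 1 rose in footprints (median -0.15, permutation p = 0.000755). Chac1, which degrades glutathione, fell by -1.76 (FDR 3.14e-05) in mRNA and -1.42 (FDR 0.000392) in footprints in the authors' deposited table. Of 24 genes of the unfolded protein response 10 fell in mRNA (median -0.20, permutation p = 0.00085), 16 over the list alone, and 6 in footprints (median -0.11, permutation p = 0.000755), with Herpud1 at -1.18 (FDR 0.000139) in mRNA in the authors' deposited table. Of 26 cholesterol genes 13 fell and 2 rose in mRNA (median -0.25, permutation p = 0.00085), 16 and 3 over the list alone, and 8 fell in footprints (median -0.17, permutation p = 0.000755). The sterol regulator Srebf2 fell by -0.48 (FDR 3.36e-05) and Dhcr7 by -0.51 (FDR 0.000107) in the authors' deposited table. Of 15 Wnt pathway genes 6 fell in mRNA (median -0.14, permutation p = 0.0408), among them the co-receptor Lrp5 (-0.50, FDR 6.88e-05) in the authors' deposited table, but the median did not pass with unmatched random lists (permutation p = 0.248).

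Some cytosolic heat shock and ribosome biogenesis genes rose after RPLP1 removal. Of 21 cytosolic heat shock genes 7 rose and 1 fell in mRNA (median 0.09, permutation p = 0.174) and 6 rose and 1 fell in footprints (median 0.09, permutation p = 0.0102). Dnaja1 (0.47, FDR 1.74e-05), Chordc1 (0.46, FDR 0.000133) and Hsph1 (0.40, FDR 0.000189) rose in mRNA in the authors' deposited table. Ribosome biogenesis had 8 of 68 genes higher and none lower in each assay, with medians of 0.09 for mRNA (permutation p = 0.0408) and 0.07 for footprints (permutation p = 0.0187). Nop58 rose by 0.28 (FDR 0.0042) in mRNA and 0.22 (FDR 0.00783) in footprints, per the authors' deposited table. Of 13 mitochondrially encoded mRNAs 6 fell and 2 rose (median -0.13, permutation p = 0.00085), whereas 3 rose in footprints (median 0.05, permutation p = 0.495); the mRNA median did not pass with unmatched random lists (permutation p = 0.312). Of 16 fibroblast markers, included because cultures can hold feeder cells, 1 fell in mRNA and 3 in footprints, namely Mmp2 (-0.33, FDR 0.0109), Thy1 (-0.60, FDR 0.0226) and Col5a1 (-0.26, FDR 0.0415) in the authors' deposited table. Their footprint median did not pass among precisely measured members (permutation p = 0.389), and lay below that of RPLP0 by a median difference of -0.31 (permutation p = 0.0457). The mRNA difference from RPLP0 was -0.11 and did not pass (permutation p = 0.753).

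**Figure D2:**
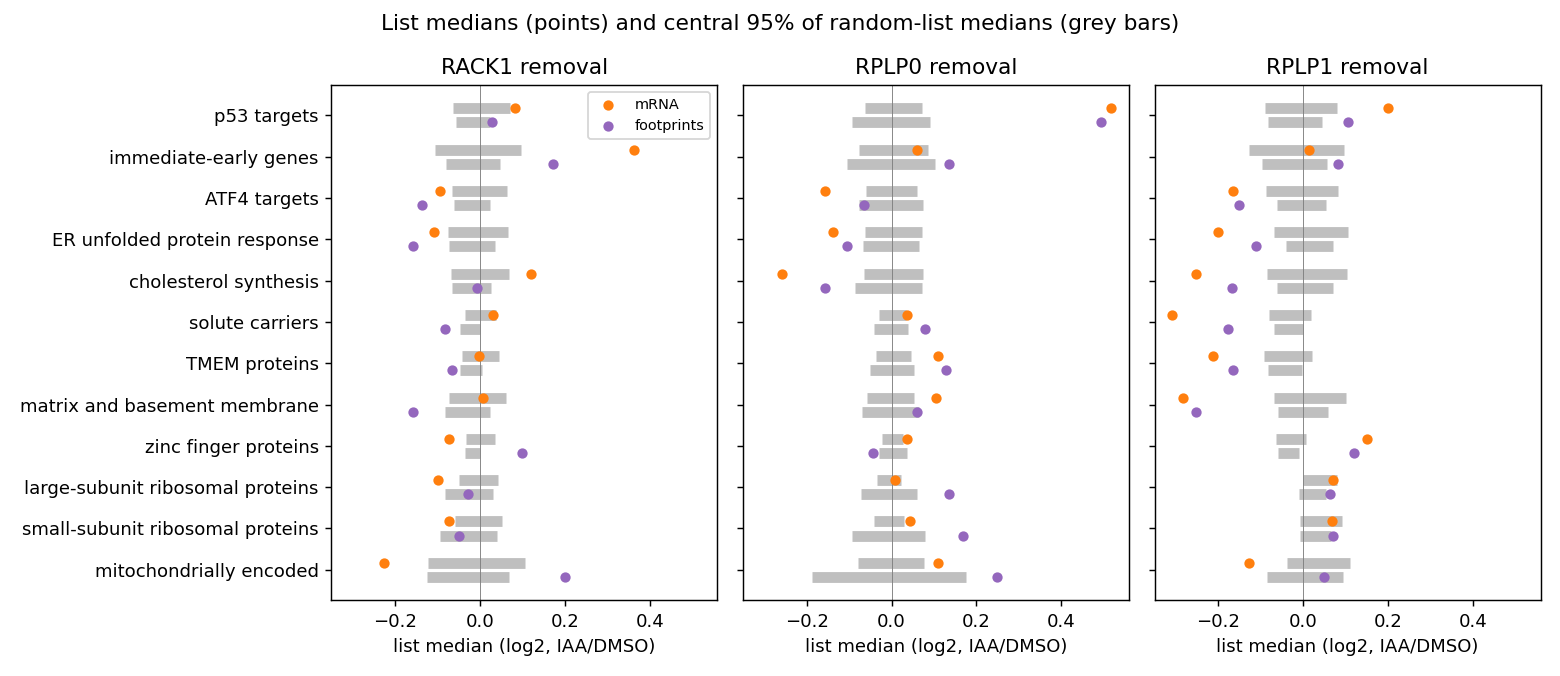
Median log2 change of 12 gene lists (points; mRNA and footprints) after removal of RACK1, RPLP0 and RPLP1, with grey bars for the central 95% of medians of random lists matched on precision. p53 targets stand furthest right in RPLP0 (0.52 for mRNA), and solute carriers furthest left in RPLP1 (-0.31 for mRNA).

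In all, 1746 mRNAs changed after RPLP1 removal, 692 higher and 1054 lower, and 1030 genes changed in footprints, 435 higher and 595 lower. Of these, 559 passed in both assays, 557 of them in the same direction. The largest mRNA changes in the authors' deposited table were increases of Ccdc103 (2.74, FDR 0.0469), Dnah11 (2.32, FDR 0.0437) and Lyrm1 (2.29, FDR 0.00665), and decreases of Pcdhga3 (-2.74, FDR 0.00341), Htr6 (-1.96, FDR 0.0418) and Chac1. Protocadherin gamma genes such as Pcdhga3 share exons, so that value is uncertain. The largest footprint increases were Rag1 (3.42, FDR 0.00329) and Zfp648 (3.08, FDR 0.00185) and the largest decreases Inhbe (-1.82, FDR 0.012) and Rnf225 (-1.65, FDR 0.0359), in the authors' deposited table.

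Translation efficiency passed the added approximate test for 4 genes after RPLP1 removal, all higher. They were Utf1, a chromatin factor of pluripotent cells (0.44, SE 0.09), mt-Cytb (0.43, SE 0.08), Chchd10 (0.41, SE 0.09) and Mif (0.37, SE 0.08). At an unadjusted p below 0.05 there were 905 genes, and with an error correlation of 0.5 between assays 473 passed. Lists with higher efficiency were mitochondrially encoded genes (median 0.22, permutation p = 0.00340), solute carriers (0.12, permutation p = 0.00340) and the unfolded protein response (0.08, permutation p = 0.0317).

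RPLP0 and RPLP1 belong to the same stalk, and their removal gave calls in the same direction and in opposite directions. Among 11967 genes measured in both lines, 79 mRNAs rose in both (35.6 expected for independent lists, Fisher's exact p = 1.51e-11) and 110 fell in both (53 expected, Fisher's exact p = 4.83e-14), while 112 were called in opposite directions (88.9 expected). In footprints 31 rose in both (6.08 expected, Fisher's exact p = 4.74e-14), 27 fell in both (6.28 expected, Fisher's exact p = 8.73e-11) and 3 went opposite ways (13 expected), a count that was 50 (64 expected) at an FDR below 0.1. Of p53 targets 15 rose in mRNA in both lines, against 11.7 expected from the list's own calls in each line. For the ATF4, unfolded protein response and cholesterol lists, 6 genes each fell in mRNA in both lines, against 3.76, 4.17 and 6 expected in the same way; these list overlaps were not tested. Across genes, the Spearman correlation of the 2 responses was 0.0918 for mRNA and 0.0207 for footprints.

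**Figure D3:**
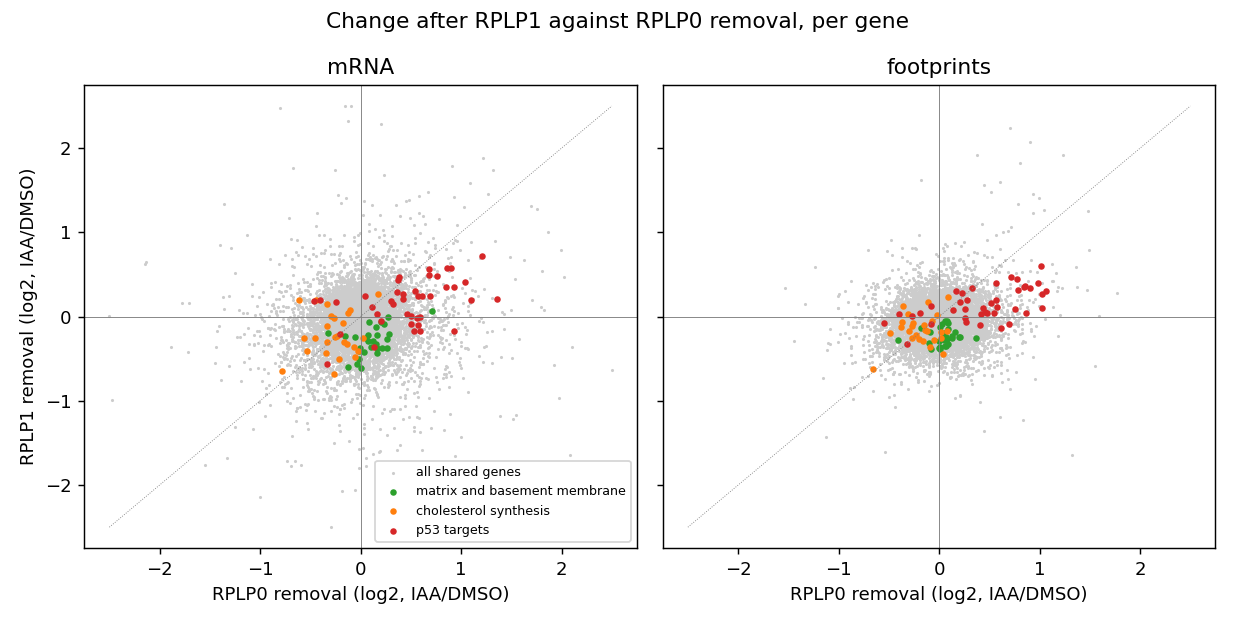
Log2 change after RPLP1 removal (vertical) against RPLP0 removal (horizontal) per gene, for mRNA and footprints, with values beyond 2.5 drawn at 2.5; each point is 1 gene measured in both lines, and the dotted line marks equal change. Most p53 targets lie right of 0 and below the dotted line (median mRNA 0.52 in RPLP0, 0.20 in RPLP1), and matrix genes lie below 0 on the vertical axis only (median mRNA -0.28 in RPLP1).

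Responses were compared directly with the added approximate test. Between RPLP0 and RPLP1, 1460 genes differed in mRNA response, 570 in footprints and 1 in translation efficiency. The laminin gene Lamc1 differed by -0.58 in mRNA (RPLP1 minus RPLP0, SE 0.09), Col18a1 by -0.62 (SE 0.11) and Slc7a5 by -0.58 (SE 0.12). Between RACK1 and RPLP0, 403 genes differed in mRNA, 82 in footprints and 8 in translation efficiency; between RACK1 and RPLP1, 961, 13 and 39. RACK1, with fewer calls, shared these with the other lines: 3 mRNAs rose (1.12 expected, Fisher's exact p = 0.0990) and 4 fell (1.86 expected, Fisher's exact p = 0.112) with RPLP0, and 1 rose (1.24 expected, Fisher's exact p = 1) and 7 fell (3.21 expected, Fisher's exact p = 0.0374) with RPLP1. The last overlap did not pass at an FDR below 0.01 (1 shared, Fisher's exact p = 0.470) or below 0.1 (12 shared, 7.81 expected, Fisher's exact p = 0.123). Pck2 fell in footprints after both RACK1 and RPLP1 removal, the 1 footprint call those lines shared. Opposite mRNA calls numbered 9 for RACK1 and RPLP0 (2.99 expected) and 15 for RACK1 and RPLP1 (4 expected), above the calls shared in either direction added together.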

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

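The tests of differences between lines and all tests below were chosen after the results were seen, except the test of genomic span, which was set before its result. Of 204 list differences between pairs of lines, 78 passed, and the 24 given here passed in mRNA and footprints with the same direction, a selection also made after the results were seen. Values are medians of the per-gene difference of log2 changes, for mRNA and then for footprints.

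The RPLP1 response lay below the RPLP0 response for matrix genes (-0.41 and -0.30), solute carriers (-0.32 and -0.24), p53 targets (-0.29 and -0.35), TMEM proteins (-0.28 and -0.27) and nuclear-encoded respiratory chain genes (-0.0328 and -0.10), and above it for zinc finger proteins (0.0894 and 0.16). Against RACK1 the footprint differences of RPLP1 were smaller than the mRNA differences in every list given. RPLP1 lay below RACK1 for solute carriers (-0.37 and -0.11), immediate-early genes (-0.34 and -0.15), cholesterol synthesis (-0.33 and -0.13), TMEM proteins (-0.19 and -0.12) and ATF4 targets (-0.18 and -0.09). It lay above RACK1 for zinc finger proteins (0.23 and 0.02), cytosolic heat shock (0.22 and 0.20), large-subunit ribosomal proteins (0.16 and 0.09), other mRNAs with a terminal oligopyrimidine tract (0.15 and 0.13), initiation factors (0.15 and 0.10) and ribosome biogenesis (0.13 and 0.08). The RPLP0 response was above that of RACK1 for p53 targets (0.47 and 0.45), histones (0.42 and 0.16), large-subunit (0.10 and 0.18) and small-subunit ribosomal proteins (0.10 and 0.20), TMEM proteins (0.0780 and 0.17) and the nuclear-encoded respiratory chain (0.0706 and 0.11), and below it for cholesterol synthesis (-0.41 and -0.19).

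In translation efficiency 48 gene differences passed over the 3 pairs, and the 14 of genes named for their size of change, or of Pabpc1, are given here. Apart from Pabpc1, these genes were picked for a large efficiency change in a line. Their difference from other lines uses the same values, so it is no separate evidence and its size can be inflated. Relative to RACK1, the RPLP0 change was lower for Kxd1 (-2.75, SE 0.33) and Lars2 (-2.13, SE 0.29). It was also lower for Zyg11a (-1.54, SE 0.28) and Zfp609 (-0.83, SE 0.18), and higher for Pgp (0.87, SE 0.20). The RPLP1 change relative to RACK1 was lower for Kxd1 (-2.86, SE 0.32), Lars2 (-2.62, SE 0.29) and mt-Nd3 (-1.63, SE 0.24). It was also lower for Zyg11a (-1.54, SE 0.29) and Zfp609 (-0.88, SE 0.18). The RPLP1 change was higher for Pabpc1 (0.87, SE 0.22), Utf1 (0.86, SE 0.16) and Pgp (0.79, SE 0.20). Pabpc1, the poly(A)-binding protein, named after its values were seen, was also higher in RPLP1 than in RPLP0 (0.57, SE 0.10).

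The decrease of solute carriers, TMEM proteins and matrix genes with the increase of zinc finger proteins after RPLP1 removal was set against technical explanations. A trend with genomic span as the whole source is argued against: after its removal the list that lost most kept 0.964 of its median, with a lower bound of 0.786. The footprint medians lay outside random lists on the same side as mRNA for 4 of the 4 lists. These lists were picked for moving in both assays, so this is no separate test of a bias of the mRNA libraries alone. Base composition stays open, since the sequences of 0 genes are used here, as does the removal of RPLP1 itself, an untested biological explanation. For the matrix part a change in cells of another type also stays open. Fibroblast markers had a median of -0.27 in mRNA, which did not pass. Their footprint median of -0.22 passed, but not among precisely measured members. The tables give no expression levels that would bound the share of such cells.

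The larger increase of p53 targets after RPLP0 than after RPLP1 removal was set against smaller fold changes throughout the RPLP1 table and against the mRNA libraries alone. Of 1446 genes outside the p53 list whose mRNA responses differed between these lines, 63.3% had the larger absolute change in RPLP1 (exact binomial interval 60.7 to 65.8, which treats genes as independent), which argues against a general scale. The median footprint difference was -0.35, below the -0.14 that bounds random lists. This difference was picked for passing in both mRNA and footprints, so the footprint value is no separate test of the mRNA libraries as the whole source. A biological difference between the lines and a difference in how completely each protein was removed both stay open and were not tested.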

How the results depend on the processing

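The FDR below 0.01 and the minimum log2 change of 1 were planned for the calls within a line; all other settings, and every setting for differences between lines, were chosen after the data were seen. No direction reversed under any setting run, and counts at other thresholds moved because these pass fewer or more genes by construction; with a correlation between assays they moved because it lowers the assumed standard error of translation efficiency. No paired analysis was possible because the tables hold 1 statistic per gene and no value per sample. For the same reason DESeq2, another normalization, no filter on low counts, leaving out each replicate, a culture block, a pseudocount, a filter on normalized values, and camera with a preset or estimated correlation were not run. Depth is unknown, so which results it limits cannot be said.

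At an FDR below 0.01 the changed mRNAs numbered 28 (RACK1), 653 (RPLP0) and 752 (RPLP1), the footprints 71 (RPLP0) and 113 (RPLP1), and translation efficiency 5 (RACK1) and 0 (RPLP0). RACK1 footprints (3) and RPLP1 translation efficiency (3) stayed within 1.5 times. With an absolute log2 change of at least 1 there were 11, 44 and 30 mRNAs, 0, 28 and 30 footprint genes, and 5, 0 and 0 for translation efficiency, in the order RACK1, RPLP0, RPLP1. The authors' class codes gave 286, 2738 and 3956 mRNAs and 81, 860 and 1840 footprint genes. With an error correlation of 0.5 between assays translation efficiency passed for 421, 245 and 473 genes, and differed for 205 (RPLP0 and RPLP1), 512 (RACK1 and RPLP0) and 798 (RACK1 and RPLP1).

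Differences between lines at an adjusted p below 0.01 numbered 706 in mRNA and 48 in footprints for RPLP0 and RPLP1, 142, 19 and 3 (translation efficiency) for RACK1 and RPLP0, and 321, 5 and 12 for RACK1 and RPLP1. With a difference of at least 1 they numbered 62 and 20, 44 and 9, and 97 and 2, for mRNA and footprints. Calls shared by RPLP0 and RPLP1 at a threshold of 0.1 were 147 mRNAs higher (82.9 expected), 182 lower (106 expected), 46 footprint genes higher (28.6 expected) and 75 lower (35.1 expected), each a smaller ratio to expectation than at 0.05, with 211 mRNAs (190 expected) and 50 footprint genes (64 expected) in opposite directions. Of 400 calls of named genes 231 passed at 0.01 and 169 did not. Of 108 list calls 78 passed with unmatched random lists and 30 did not; of those with enough precisely measured members 83 passed and 19 did not, and the cause was not tested.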

Other observations

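The tests of carry-over and of the 4 lists in the correlation were set before their results; the other tests below were chosen after the results were seen.

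Other gene groups are given here. After RACK1 removal cholesterol synthesis mRNAs had a median of 0.12 (permutation p = 0.0034), and large-subunit ribosomal proteins (-0.10, permutation p = 0.00272) and other mRNAs with a terminal oligopyrimidine tract (-0.09, permutation p = 0.0068) were lower, none of which passed with unmatched random lists (permutation p = 0.0909, 0.0714 and 0.197). After RPLP1 removal 10 of 50 large-subunit ribosomal protein mRNAs rose and 3 fell (median 0.07, permutation p = 0.303; adjusted Fisher's exact p = 0.00227 for the increases), 12 and 4 adjusted over the list alone, and 5 of 30 small-subunit mRNAs rose and none fell (0.07, permutation p = 0.525). Their footprint medians were 0.06 (permutation p = 0.0187) and 0.07 (permutation p = 0.0445), the second not past with unmatched random lists (permutation p = 0.0552). Of 79 nuclear-encoded respiratory chain mRNAs 11 fell and 3 rose in that line (0.00, permutation p = 0.302), 12 and 3 over the list alone, with a footprint median of -0.02 (permutation p = 0.000755; 0.620 with unmatched random lists). Initiation factors were higher there in footprints (0.08, permutation p = 0.00272; 4 of 46 rose). Mitosis genes had a footprint median of -0.10 in RPLP0 (permutation p = 0.000755) and 0.08 in RPLP1 (permutation p = 0.0131), with no called member in either. In RPLP0, stalled-ribosome rescue factors had a footprint median of -0.08 (permutation p = 0.0304), mitochondrial ribosomal proteins 0.05 (permutation p = 0.00732), and proteasome subunits an mRNA median of -0.05 (permutation p = 0.048); none passed with unmatched random lists (permutation p = 0.118, 0.113 and 0.245). mRNAs controlled by upstream open reading frames had mRNA medians of 0.01, 0.05 and 0.01 in RACK1, RPLP0 and RPLP1 (permutation p = 0.869, 0.27 and 0.91), but members went both ways: 6 of 20 rose and 2 fell in RPLP0 (adjusted Fisher's exact p = 0.00387 for the increases; 7 and 3 adjusted over the list alone), and 3 rose and 1 fell in RPLP1. In RPLP0 they included Mdm2, also a p53 target, and Ifrd1 among the increases and Ibtk among the decreases. Elongation and termination factors had -0.03, 0.03 and 0.08 (permutation p = 0.686, 0.467 and 0.478), and aryl hydrocarbon receptor targets -0.04, -0.07 and 0.08 (permutation p = 0.824, 0.467 and 0.57).

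After RACK1 removal, histone and mitochondrially encoded mRNAs, both poor in long poly(A) tails, were lower without lower footprints. A candidate explanation is carry-over of RNA without a poly(A) tail in the control mRNA libraries: 9 polyadenylated histone variants had a median of 0.0341 (-0.08 to 0.10), as this needs. Of those 9, 1 is also in the histone list. Without it, a choice made after the result was seen, the median was 0.05. A true fall of replication-dependent histone mRNAs could also leave these variants unchanged. The variants therefore do not favour carry-over over a true fall, and both stay open. Imprecise genes are argued against for the mitochondrial part, where 13 of 13 members were in the more precise part of the table, and stay open for the histones, with 1 of 41. Mitochondrial footprint medians stood at or above percentile 99.75 in RACK1 and RPLP0. In RACK1 the mRNA median was -0.23 and the footprint median 0.20, so the mRNA change alone does not account for the footprints there. In RPLP0 both medians were higher, 0.11 for mRNA and 0.25 for footprints, so the percentile cannot exclude the mRNA change as the source. Among precisely measured members the RPLP0 efficiency median was 0.03. Fewer cytosolic footprints per cell were not measured and would raise the footprint medians in all lines. They stay open, with footprint medians above random lists in 2 of 3 lines.

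Footprint changes after RACK1 and RPLP1 removal correlated across genes (Spearman 0.234), while their mRNA changes (-0.146) and translation efficiency changes (-0.123) correlated negatively; genes are not independent replicates. Without the 753 listed solute carriers, TMEM proteins, matrix genes and zinc finger proteins the correlation was 0.212 over 11381 genes, so these listed genes alone do not carry it. They were few of 12134 genes. Other membrane, secreted or zinc finger genes stay among the 11381, so whether such wider classes carry the correlation was not tested.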
